A study of Mus musculus with 6 samples.

How the data were processed

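RNA sequencing measured gene expression in 6 libraries of cultured mouse cells, 2 in each of 3 groups. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

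The deposited values are expected counts, that is estimated counts of reads per gene, per the file headers, made by the authors before deposit by aligning reads with HISAT to the mouse genome build mm9, per the submitters' processing notes. Each gene is given as an NCBI gene number, and the values are not scaled for library size. The version of the aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. About 32.4% to 32.8% of the values in a library were not whole numbers, as happens where reads that match several genes are split between them. Genes with such values are therefore less certain, and reads of overlapping or antisense genes cannot be told apart. The tables held 18305 genes. A symbol was found by gene number for 18179 of them in an NCBI RefSeq gene table of the assembly GRCm38.p6. The 126 unmatched gene numbers held between 0.164% and 0.259% of the reads of a library. Since that assembly is not the build of the counts, only names were taken from it and no positions are given. Hsd17b3 and Xist, which the rule for named genes also lists, are not analysed here, and some further genes that the rule names are not reported.

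Total estimated reads ranged from 18.4 to 18.9 M per library, and between 16441 and 16631 genes were above 0. The libraries of each group were compared by a chi-square of their counts over genes with whole values and at least 20 reads in the pair. The chi-square per degree of freedom was 1.80 for CiLC, 2.77 for MEF and 2.94 for LC, above the value of 1 for sampling noise alone, so no pair looked like a library deposited again, and both libraries were kept. This does not show separate samples: repeat libraries of a culture can exceed sampling noise too, and the excess was largest in genes with the most reads (7.26 to 24.1, against 1.23 to 1.47 in genes with fewer reads). A floor of 3 reads summed over the libraries of a group was used for genes at 0. A fold against a group at 0 is a lower bound against that floor. For 1 to 3 reads in the lower group, a ratio of counts with an exact 95% binomial interval is given. Intervals cover counting error only, and floors only the counting error of the lower group.

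Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14581 genes and removed 3724. Libraries were scaled by the trimmed mean of M values. All 6 libraries entered a single quasi-likelihood fit with group as the only term (glmQLFit and glmQLFTest), and the groups shared the estimate of spread. The common biological coefficient of variation was 3.16%, a low value. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison, and genes were called at an adjusted p of 0.05. Log2 fold changes carry a prior count of 0.125. Standard errors were computed from the fitted weights and the moderated quasi-dispersion. Levels are CPM, computed with the scaled library sizes, as mean ± SD of the 2 libraries. On data simulated from the MEF means for the comparison of CiLC with MEF, with 50 genes changed at each fold among genes with a mean of at least 10 reads, the procedure recovered 40% of genes changed by 1.2-fold, 84% of those changed by 1.5-fold, 78% of those changed by 2-fold and 98% of those changed by 4-fold. It made 5 false calls among 14469 genes, and no call in the simulated comparison without change. The simulated spread was the one fitted to these libraries, most genes were unchanged, and genes with any read were kept in place of filterByExpr. These rates therefore do not cover variation between cultures or data in which most genes change. The limit of 10 reads was set after a first run of the simulation had drawn genes that the filter removes.

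Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. Of 31 lists, the erythroid and the skeletal muscle list had 2 tested members each and could not be tested as lists. The other 29 were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 29 lists and 3 comparisons, and again with the correlation estimated from the data. With an estimated correlation camera uses the residual degrees of freedom of the fit, which are few here. A call lost in that setting therefore does not by itself show that the members of a list were correlated. Counts of called members are given over all genes tested. Adjusted over the list alone, they differed by at most 1 member from that count in either direction.

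Genes were named by a fixed rule. Star, Cyp11a1, Hsd3b1, Cyp17a1, Lhcgr, Nr5a1 and Insl3 are reported in every comparison. In each comparison, the 6 called genes with the highest and the 6 with the lowest log2 fold change were named, among genes with a symbol that is not predicted or clone-based, at least 5 CPM in the higher group and no overlap between the groups. Called members of each list with the largest absolute change were named, up to 4 for the steroid hormone, Leydig cell, cholesterol and fibroblast lists and up to 2 for the others. A list could be given with fewer examples. Y-linked genes were read as a check of the labels. Genes named outside this rule were chosen after their values were seen, and the text says so.

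Similarity of libraries was measured by Pearson correlation across tested genes of log2(CPM + 1). Overlap of calls against MEF was set beside the product of both numbers of calls divided by the genes tested, and beside 20 simulations of unchanged groups that share the MEF libraries. The settings tried in place of these were no filter, a mean of at least 5 CPM, DESeq2 size factors, quantile normalization with limma, DESeq2 1.42.0 as the test, only the 4 libraries compared, the replicate number as a block, stricter thresholds and leaving out each library in turn. An assumed biological coefficient of variation of 0.1 or 0.4, with edgeR's likelihood ratio test, was added after seeing the data, because the replicates were so alike. For a list or gene with a test, any change of direction was counted as a reversal, whether or not it was called. Figures were drawn with matplotlib 3.10.9.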

Results

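Gene expression was measured by RNA sequencing in cultured cells of KM mice. MEF are embryonic fibroblasts taken at 12.5 or 13.5 days of gestation and grown for 3 to 5 passages. CiLC are such fibroblasts treated with small molecules from 24 hours after seeding. LC are Leydig cells, the androgen-producing cells between the tubules of the testis, isolated from testis and grown for 0 to 1 passages. Each group had 2 libraries, with 18.4 to 18.9 M estimated reads each. The series set the groups beside each other to ask how closely CiLC resemble LC across all genes. All values with an SD below are means of 2 libraries, and adjusted p-values come from edgeR's quasi-likelihood test unless a list is named.

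The comparison of CiLC with MEF sets treated beside untreated fibroblast cultures. Star, Cyp11a1 and Hsd3b1, of the first steps of steroid synthesis, were higher in CiLC. Star (NCBI gene 20845), which moves cholesterol into mitochondria, rose 11.0-fold, from 5.28 ± 0.269 to 58.0 ± 0.61 CPM (SD, n = 2; log2 fold change 3.46 ± 0.11 SE, edgeR adjusted p = 7.85e-20). Cyp11a1 (13070), which cleaves the cholesterol side chain to make pregnenolone, rose from 1.33 ± 0.117 to 12.3 ± 0.677 CPM (log2 fold change 3.20 ± 0.22 SE, edgeR adjusted p = 5.01e-14). Hsd3b1 (15492), the dehydrogenase that makes progesterone, rose from 0.698 ± 0.274 to 6.12 ± 0.338 CPM (log2 fold change 3.11 ± 0.30 SE, edgeR adjusted p = 4.12e-11). Nr5a1 (26423), the nuclear receptor also called steroidogenic factor 1, rose from 0.157 ± 0.000786 to 69.0 ± 0.385 CPM, with 3 reads in each MEF library and 1361 and 1355 in the CiLC libraries (log2 fold change 8.72 ± 0.59 SE, edgeR adjusted p = 2.76e-22).

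The other genes reported in every comparison had few reads. Cyp17a1 (13074), which makes androgen precursors, had at most 1 read in each CiLC and MEF library. Lhcgr (16867), the receptor for luteinizing hormone, had 0 reads in CiLC and 0 and 1 in MEF. No fold is given for either gene. Insl3 (16336), a peptide hormone of Leydig cells, had 18.5 and 3.44 estimated reads in CiLC and 0 and 37.0 in MEF (edgeR adjusted p = 0.406). Of its values, 4 were not whole, and its direction rested on a single library: the log2 fold change was -0.78 with all libraries and 6.39 without MEF replicate 2. Without MEF replicate 1, it was -1.78 with an adjusted p of 0.00599.

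Of 16 tested members of the steroid hormone synthesis list, 9 rose, none fell and 7 were not called (median log2 fold change 0.30). The list was called with camera (adjusted p = 6.97e-06), but not with an estimated correlation (adjusted p = 0.121). Akr1c14, a hydroxysteroid dehydrogenase, rose from 0.784 ± 0.226 to 35.4 ± 1.6 CPM. Hsd11b1, which regenerates active glucocorticoids, rose from 0.105 ± 0.0744 to 4.12 ± 0.872 CPM. Fdx1 and Fdxr, which feed electrons to Cyp11a1, were chosen here after their values were seen and showed no clear rise. The log2 fold change of Fdx1 ran from -0.064 to 0.23 with single libraries left out. Fdxr was called only with quantile normalization, as lower (log2 fold change -0.259, limma adjusted p = 0.023). Of 23 tested members of the Leydig cell identity list, 12 rose, 5 fell and 6 were not called, with 13 rising when adjusted over the list alone (camera adjusted p = 1.99e-06; adjusted p = 0.0471 with an estimated correlation). Gata4, a transcription factor of gonadal somatic cells, rose from 3.89 ± 0.0913 to 72.1 ± 0.213 CPM. Ptgds, a prostaglandin synthase, rose from 0.131 ± 0.0376 to 27.4 ± 4.31 CPM, and the prolactin receptor Prlr from 3.95 ± 0.641 to 90.2 ± 2.26 CPM. The adrenal cortex list shares Star, Cyp11a1, Hsd3b1 and Nr5a1 with these lists, and 5 of its 8 tested members rose (camera adjusted p = 9.09e-09; adjusted p = 0.0439 with an estimated correlation). The cholesterol synthesis and uptake list was not called (camera adjusted p = 0.188), although 11 of 24 members rose and 1 fell. It was called as higher without a filter (adjusted p = 0.0186), with quantile normalization (0.0394), with only the 4 libraries compared (0.0372), with the replicate number as a block (0.0298) and without LC replicate 1 (0.0396) or LC replicate 2 (0.0383). Among the members that rose, Stard4, a cholesterol carrier, rose 1.72-fold and the sterol oxidase Msmo1 1.39-fold. Idi1, an isomerase of the pathway, rose 2.15-fold, from 1.72 ± 0.519 to 3.71 ± 1.82 CPM (edgeR adjusted p = 0.00196), a call lost with DESeq2 (adjusted p = 0.0603), without CiLC replicate 1 (0.189) and without MEF replicate 2 (0.0614).

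**Figure D1:**
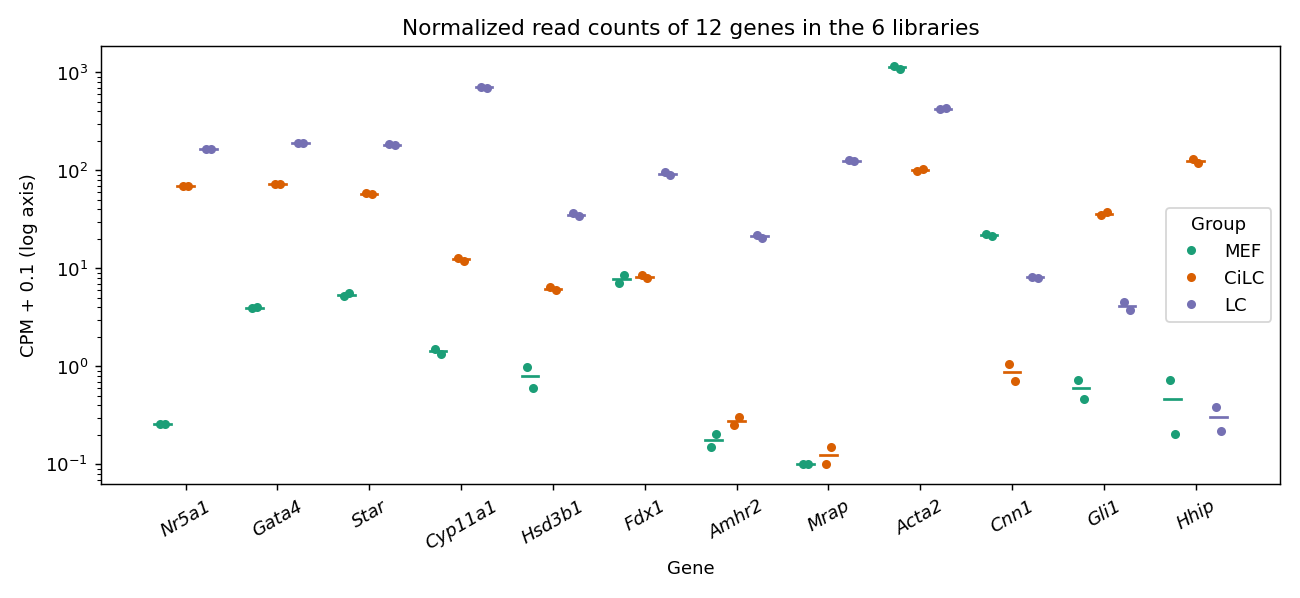
Normalized read counts of 12 genes, as CPM plus 0.1 on a log axis, in the 2 libraries of each group (points) with the mean of both (bars). Nr5a1, Gata4, Star, Cyp11a1 and Hsd3b1 in CiLC lay between MEF and LC, while Amhr2 and Mrap were near 0 in MEF and CiLC, and Hhip was at 125 CPM in CiLC alone.

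Contractile genes fell together. All 15 members of the smooth muscle and contractile list were lower in CiLC than in MEF (median log2 fold change -2.20; camera adjusted p = 4.2e-45; adjusted p = 0.029 with an estimated correlation). Cnn1, an actin-binding calponin, fell from 21.7 ± 0.7 to 0.788 ± 0.253 CPM, and Myh11, smooth muscle myosin, from 29.7 ± 1 to 1.45 ± 0.105 CPM. The pericyte gene Rgs5, of the peritubular and stromal list, fell 65.1-fold, from 74.9 ± 8.94 to 1.14 ± 0.177 CPM. Of 20 members of the TGF-beta response list, 17 fell and 1 rose, or 2 when adjusted over the list alone (camera adjusted p = 3.01e-13; adjusted p = 0.029 with an estimated correlation). Ankrd1 fell 15.2-fold and Ccn2, a matrix-associated growth factor, 5.52-fold. In the fibroblast and extracellular matrix list, 22 of 35 members fell and 9 rose (camera adjusted p = 3.25e-05; adjusted p = 0.122 with an estimated correlation). Tenascin C (Tnc) fell from 3533 ± 79.3 to 361 ± 10.3 CPM, elastin (Eln) from 964 ± 61.2 to 110 ± 9.18 CPM and fibronectin (Fn1) 3.26-fold, whereas lumican (Lum) rose 4.07-fold. Cell cycle genes fell by less: 27 of 30 members were lower and 1 higher, with a median log2 fold change of -0.40 (camera adjusted p = 0.00048; adjusted p = 0.0646 with an estimated correlation). Aurkb fell 1.90-fold and Bub1b 1.78-fold.

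Hhip and Gli1, which hedgehog signalling induces, rose. Hhip, a membrane antagonist of the pathway, went from 0.367 ± 0.371 to 125 ± 8.75 CPM (edgeR adjusted p = 8.66e-22), and the effector Gli1 from 0.497 ± 0.188 to 36.1 ± 1.55 CPM. The hedgehog receptor Ptch1, chosen after its values were seen, rose to 74.2 ± 2.16 CPM (log2 fold change 1.96 ± 0.079 SE). Of 17 tested members of the Wnt and hedgehog response list, 11 rose and 4 fell (camera adjusted p = 8.14e-05; adjusted p = 0.0586 with an estimated correlation). Wif1, an inhibitor of Wnt ligands that is not on this list, had 0 and 2 reads in MEF and 458 and 383 in CiLC. That is a ratio of 409 with a counting interval from 113 to 3380. The imprinted growth network list had 13 members higher and 2 lower of 16, or 3 lower when adjusted over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.0539 with an estimated correlation). Dlk1 rose 3.23-fold and Mest 3.08-fold. In the epithelial list, 6 of 9 tested members rose and 1 fell (camera adjusted p = 0.000156; adjusted p = 0.0981 with an estimated correlation), among them the keratins Krt8, from 0.13 ± 0.11 to 5.21 ± 0.336 CPM, and Krt18, from 0.888 ± 0.00445 to 19.7 ± 1.02 CPM.

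Lists of lipid, oxidative and immune genes also moved. Of 23 members of the lipid storage and export list 15 rose and 2 fell, or 3 when adjusted over the list alone, with the fatty acid transporter Cd36 up 7.94-fold. Of 8 adipocyte members 6 rose, with lipoprotein lipase (Lpl) up from 189 ± 13.4 to 1771 ± 5.95 CPM. Of 18 NRF2 antioxidant members 13 rose and 2 fell, with superoxide dismutase Sod2 up 3.91-fold. Of 18 interferon response members 13 rose and 1 fell, with Gbp3 up 4.06-fold, and of 22 members of the glycolysis and hypoxia list 14 rose and 2 fell, with Adm up 2.77-fold. Of 21 inflammatory cytokine members 10 rose and 8 fell, with the matrix protease Mmp3 up from 12.9 ± 2.87 to 490 ± 3.11 CPM and the neutrophil attractant Cxcl5 up 25.2-fold. Camera called each of these 6 lists as higher (adjusted p from 0.000211 for lipid storage to 0.0208 for interferon). With an estimated correlation none was called (adjusted p from 0.0725 for inflammatory cytokines to 0.254 for glycolysis and hypoxia). That correlation was negative for inflammatory cytokine (-0.0091), NRF2 (-0.0142) and adipocyte genes (-0.0283), which argues against correlated members as the cause for these lists. It was positive for interferon (0.0167), lipid storage (0.0986) and glycolysis and hypoxia genes (0.0877).

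Markers of other cell types were read in the same way. Macrophage genes were abundant in all groups, with Csf1r at 1290 ± 35.2 CPM in MEF, 927.6 ± 12.6 in CiLC and 340 ± 7.12 in LC. Of 20 members 5 rose, 9 fell and 6 were not called (10 fell when adjusted over the list alone). Cx3cr1, a chemokine receptor, fell from 590.3 ± 11.4 to 80.8 ± 1.97 CPM and the complement gene C1qb from 474 ± 14 to 151 ± 3.08 CPM. Marco, a scavenger receptor of macrophages that is not on this list, had 1 and 0 reads in MEF and 333 and 318 in CiLC. That is a ratio of 633 with a counting interval from 113 to 25000. Neural genes fell in 6 of 10 cases, with nestin (Nes) down 10.4-fold, and chondrocyte and osteoblast genes fell in 6 of 9, with 1 higher. Type II collagen (Col2a1) fell from 8.3 ± 0.697 CPM to 3 reads, a ratio of 109 with a counting interval from 37 to 531. Peritubular and stromal genes split 8 higher to 7 lower, with a median log2 fold change of 0.22 and a mean of -0.72. Of 14 Sertoli cell members 6 rose and 2 fell, with the inhibin subunit Inhbb up 14.8-fold, and of 21 cyclic AMP response members 7 rose and 11 fell, with the coactivator Ppargc1a up 4.46-fold. Camera called the Sertoli list as higher (adjusted p = 0.00641) and the macrophage (0.006), neural (8.42e-05), chondrocyte and osteoblast (0.000399), peritubular (0.00218) and cyclic AMP (0.01) lists as lower. None of these calls held with an estimated correlation (adjusted p from 0.0623 for neural to 0.254 for peritubular genes). The macrophage, Sertoli, peritubular, cyclic AMP and inflammatory cytokine calls also ended without either LC library (adjusted p from 0.0936 to 0.792 without LC replicate 2). All of these but the Sertoli call also ended without CiLC replicate 1, at 0.0823, 0.335, 0.0705 and 0.089. All 5 were lost without a filter (adjusted p from 0.116 to 0.819), with quantile normalization (0.0734 to 0.834), with only the 4 libraries compared (0.099 to 0.77) and with the replicate number as a block (0.0928 to 0.798). The glycolysis and hypoxia call was lost with an assumed coefficient of variation of 0.1 (adjusted p = 0.0812).

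The other lists were not called between CiLC and MEF: endothelial (4 higher and 4 lower of 12; camera adjusted p = 0.0927), germ cell (2 higher and 1 lower of 6; 0.793), unfolded protein and amino acid stress (9 higher and 4 lower of 21; 0.96), p53 response and senescence (5 higher and 9 lower of 18; 0.332), Hox genes (6 higher and 14 lower of 31; 0.186) and oxidative phosphorylation (10 higher and 2 lower of 28; 0.332). Adjusted over the list alone, 15 Hox genes were lower and 1 gene of oxidative phosphorylation. The Hox list was called as lower without a filter (adjusted p = 0.0374), with only the 4 libraries compared (0.0308), with the block (0.0445) and without LC replicate 1 (0.0343) or LC replicate 2 (0.033). The endothelial list was called over genes of at least 5 CPM (adjusted p = 0.000487). Individual members still passed edgeR's test. Kdr, an endothelial growth factor receptor, fell 7.64-fold, the stress factor Atf3 fell 3.67-fold, and Ddx4, an RNA helicase of germ cells, rose 6.06-fold to 3.2 ± 0.208 CPM. Among other members with the largest changes, Col10a1 of growth cartilage fell 27.1-fold, the glial filament gene Gfap 9.08-fold, the skeletal troponin Tnnt3 5.79-fold, the stress cytokine Gdf15 2.26-fold and Hoxb2 2.09-fold. Gsta3 rose 4.51-fold, Iigp1 3.77-fold, the angiogenic factor Vegfa 1.88-fold, the death receptor Fas 1.79-fold, Slc7a11 1.76-fold and Cox6c 1.56-fold. Plin1, which coats lipid droplets, had 0 reads in MEF and rose at least 3.24-fold, a call lost with quantile normalization (adjusted p = 0.104). Calls of several list members at low counts were less stable. Sox18 rose from 1 and 0 reads to 3 and 7 (ratio 9.72, counting interval 1.38 to 422), and Aard, a testis gene, fell from 6 and 3 reads to 0 and 1 (ratio 9.25, counting interval 1.28 to 406). Vgf rose 5.23-fold, Hoxd11 1.89-fold and Sycp1, of the meiotic synaptonemal complex, 1.83-fold. The Sox18 call was lost without MEF replicate 2 (adjusted p = 0.155), without CiLC replicate 2 (0.207), without a filter (0.0571), with quantile normalization (0.193) and with DESeq2 (0.114). That of Aard was lost without MEF replicate 1 (adjusted p = 0.147), without CiLC replicate 1 (0.144), with quantile normalization (0.0672), with DESeq2 (0.085) and with only the 4 libraries compared (0.0514). Vgf lost its call without MEF replicate 2 (adjusted p = 0.055) and without CiLC replicate 1 (0.279), and Sycp1 without MEF replicate 2 (0.0787) and with DESeq2 (0.0863). Hoxd11 lost its call without MEF replicate 1 (adjusted p = 0.321), without any CiLC or LC library (0.057 to 0.179), without a filter (0.063), with DESeq2 (0.0916), with only the 4 libraries compared (0.086) and at an assumed coefficient of variation of 0.1 (0.0796). The remaining genes with the largest rises were Mup20, at least 142-fold higher, and the chemokine Cxcl13, at least 67.1-fold higher, both with 0 reads in MEF. Treml2 fell 70.5-fold, Hs3st5 59.8-fold and Sema5b 57-fold, and Cst7 went from 12.3 ± 0.308 CPM to 7 and 1 reads. Folds at low counts moved when a library was left out. The log2 fold change then ran from -7.75 to -5.09 for Cst7, -5.88 to -4.14 for Col10a1, -3.17 to -2.10 for Tnnt3, 2.02 to 3.58 for Ddx4, 1.64 to 3.02 for Gsta3, 7.62 to 10.13 for Hhip, 4.65 to 6.13 for Hsd11b1, 4.6 to 6.46 for Krt8, 1.18 to 3.04 for Vgf and 0.49 to 1.53 for Idi1.

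In all, 3808 genes were higher and 3721 lower in CiLC than in MEF of 14581 tested, and 908 and 872 of them changed at least 2-fold. With a biological coefficient of variation of 0.1 assumed for every gene, chosen after seeing the data, the counts were 2064 and 2141, and with 0.4 they were 407 and 268. Among named genes, the calls of Aard, Adm, Aurkb, Bub1b, C1qb, Cox6c, Dlk1, Fas, Fn1, Gdf15, Gsta3, Hoxb2, Hoxd11, Idi1, Mest, Msmo1, Slc7a11, Sox18, Stard4, Sycp1, Vegfa and Vgf were lost at 0.4 (adjusted p from 0.0615 for Gsta3 to 1). No list was called with the block and an estimated correlation together (adjusted p from 0.123). Estimated reads of Hsd3b1, Prlr, Mest, Lpl, Sod2, Cx3cr1, Myh11, Csf1r, Mup20, Treml2, Sema5b, Gli1, Ppargc1a, Gbp3, Mmp3, Cxcl5, Adm, Eln, Idi1, Gsta3, Iigp1, Vegfa, Fas, Slc7a11 and Hoxd11 were not whole in at least 1 library, so that these levels are less certain.

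The comparison of LC with MEF sets testis-derived cells beside untreated fibroblast cultures. The named steroid genes that could be detected stood higher in LC. Cyp11a1 was at 705 ± 17.8 CPM in LC against 1.33 ± 0.117 CPM in MEF (SD, n = 2; log2 fold change 9.04 ± 0.21 SE, edgeR adjusted p = 2.95e-27). Star was at 182 ± 2.93 CPM, 34.5-fold higher (log2 fold change 5.11 ± 0.11 SE), Hsd3b1 at 35.3 ± 1.64 CPM, 49.6-fold higher (log2 fold change 5.63 ± 0.29 SE), and Nr5a1 at 165.5 ± 2.26 CPM (log2 fold change 9.98 ± 0.59 SE). Cyp17a1 had 0 and 1 reads in LC, so that no difference was detectable at this depth. Lhcgr had 3 and 2 reads, against 0 and 1 in MEF, a ratio of 5.59 with a counting interval from 0.626 to 264. Insl3 was at 6.55 ± 0.726 CPM against 0.963 ± 1.36 CPM in MEF (edgeR adjusted p = 2.04e-05), a call that DESeq2 did not make (adjusted p = 0.272).

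Of 16 members of the steroid hormone synthesis list, 14 were higher and 2 lower in LC (camera adjusted p = 1.21e-12; adjusted p = 0.0667 with an estimated correlation). Of 23 Leydig cell identity members, 19 were higher and 2 lower, or 3 when adjusted over the list alone (camera adjusted p = 2.08e-11; adjusted p = 0.029 with an estimated correlation). Amhr2, the receptor for anti-Müllerian hormone, was at 21.1 ± 0.848 CPM against 1 and 2 reads in MEF, a ratio of 270 with a counting interval from 92 to 1310. The defensin Defb36 was at least 85.7-fold higher. Cholesterol synthesis and uptake rose as a whole, with 24 of 24 members higher (median log2 fold change 2.04; camera adjusted p = 3.28e-16; adjusted p = 0.029 with an estimated correlation). Msmo1 was at 208.1 ± 3.92 against 26.1 ± 0.279 CPM, 7.98-fold higher, Idi1 7.80-fold and Fdps 7.37-fold higher, and Hsd11b1 of the steroid list was 249.1-fold higher. In the adrenal cortex list, 7 of 8 members were higher (camera adjusted p = 1.01e-15; adjusted p = 0.0305 with an estimated correlation), with Mrap, the accessory protein of the corticotropin receptor, at 126 ± 2.21 CPM in LC and 0 reads in MEF, at least 1600-fold higher.

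Matrix and growth genes stood lower in LC. Of 35 fibroblast and extracellular matrix members, 28 were lower and 7 higher (camera adjusted p = 2.79e-15; adjusted p = 0.0507 with an estimated correlation). Fibrillin 2 (Fbn2) was at 2.98 ± 0.0318 CPM in LC and 683 ± 5.9 in MEF, periostin (Postn) at 32.2 ± 3.21 and 3141 ± 168 CPM, the surface antigen Thy1 was 68.9-fold and Eln 45.7-fold lower. All 30 cell cycle members were lower (median log2 fold change -1.43; camera adjusted p = 1.45e-08; adjusted p = 0.0316 with an estimated correlation), with Ccnb2 4.83-fold and Kif20a 3.74-fold lower. The imprinted growth network had 12 members lower and 3 higher of 16 (camera adjusted p = 4.15e-10; adjusted p = 0.0305 with an estimated correlation). Dlk1 was at 1.23 ± 0.178 CPM in LC against 110 ± 4.62 in MEF, and Igf2 at 32.1 ± 0.423 against 1679 ± 62.3 CPM. Hox genes were lower in 24 of 31 cases and higher in 6 (camera adjusted p = 0.000159; adjusted p = 0.0586 with an estimated correlation). Hoxa11 had 0 reads in LC and was at least 47.7-fold lower, and Hoxa9 was 62.1-fold lower. The p53 response and senescence list had 14 members lower and 3 higher of 18 (camera adjusted p = 0.00048; adjusted p = 0.122 with an estimated correlation), with Cdkn2a 18.2-fold and Pmaip1 8.99-fold lower.

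Metabolic and immune lists were higher in LC. All 22 members of the glycolysis and hypoxia list were higher (median log2 fold change 2.43; camera adjusted p = 8.74e-40), with the mitophagy gene Bnip3 at 378 ± 6.29 against 19.7 ± 1.01 CPM and Adm 15.7-fold higher. All 18 NRF2 antioxidant members were higher (camera adjusted p = 3.48e-15), with the glutathione transferase Gsta3 at 108 ± 2.5 against 0.288 ± 0.186 CPM and Gstm1 25.1-fold higher. All 18 interferon response members were higher (camera adjusted p = 7.9e-15), with Irf7 30.5-fold and Ifi44 24.5-fold higher. Inflammatory cytokines were higher in 17 of 21 cases and lower in 4 (camera adjusted p = 6.75e-18), with the chemokine Ccl5 at 197 ± 7.94 against 0.105 ± 0.000524 CPM, and Csf3 with 1 and 0 reads in MEF and 609 and 573 in LC, a ratio of 1320 with a counting interval from 237 to 52300. With an estimated correlation the adjusted p was 0.029 for each of these 4 lists. Lipid storage and export had 14 members higher and 4 lower of 23 (camera adjusted p = 0.000355; adjusted p = 0.158 with an estimated correlation), with Angptl4 49.9-fold and Plin1 at least 39.9-fold higher.

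Sertoli cell genes were high in the LC cultures. All 14 tested members of the Sertoli cell list, the nurse cells inside the tubules, were higher in LC than in MEF (median log2 fold change 4.80; camera adjusted p = 1.66e-12; adjusted p = 0.029 with an estimated correlation). Defb19 was at least 52.6-fold and Cst12 at least 51.1-fold higher, both with 0 reads in MEF. Peritubular and stromal genes had 7 members higher and 7 lower of 15. Tcf21 was at 69.5 ± 4.59 against 0.183 ± 0.186 CPM, whereas Rgs5 was 193.8-fold lower. Camera called that list as higher (adjusted p = 0.0161) with a median log2 fold change of -0.035 and a mean of 0.748. This call was lost with an estimated correlation (adjusted p = 0.288), without either CiLC library, without either LC library and without MEF replicate 2 (adjusted p from 0.0609 to 0.585), and without a filter (0.734), with quantile normalization (0.536), with only the 4 libraries compared (0.47) and with the block (0.242). Macrophage genes were lower in 14 of 20 cases and higher in 4 (camera adjusted p = 2.84e-12; adjusted p = 0.0507 with an estimated correlation). Cx3cr1 was 14.9-fold and the mannose receptor Mrc1 11.2-fold lower. Some members were still abundant in LC: Laptm5 and Cd68, chosen after their values were seen, stood at 483.5 ± 9.46 and 203.4 ± 10.8 CPM.

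The other lists were not called between LC and MEF, with camera adjusted p from 0.201 for cyclic AMP to 0.675 for unfolded protein stress. Higher and lower members were 8 and 7 of 15 for smooth muscle, 8 and 2 of 12 for endothelial, 1 and 1 of 6 for germ cell, 2 and 5 of 9 for epithelial, 3 and 6 of 10 for neural (7 lower when adjusted over the list alone), 5 and 2 of 8 for adipocyte and 4 and 5 of 9 for chondrocyte and osteoblast genes. For signalling and stress lists they were 6 and 8 of 21 for cyclic AMP, 9 and 10 of 20 for TGF-beta, 5 and 9 of 17 for Wnt and hedgehog, 8 and 9 of 21 for unfolded protein stress and 23 and 0 of 28 for oxidative phosphorylation. The oxidative phosphorylation list was called as higher without a filter (adjusted p = 0.000222), with quantile normalization (0.00503), with only the 4 libraries compared (0.0046), with the block (0.0255) and without any single CiLC or LC library (0.000773 to 0.0076). At an assumed coefficient of variation of 0.4 the neural (adjusted p = 0.0212) and adipocyte lists (0.013) were called. Single members moved far in opposite directions. The Wnt-responsive receptor Lgr5 was 923-fold lower in LC at 0.612 ± 0.0141 CPM, and aggrecan (Acan) was 349.8-fold higher. Gfra1, found on spermatogonia, had 1 and 10 reads in LC against 92.75 ± 1.02 CPM in MEF. Dkk2 was 256.3-fold lower and Zbtb16 8.04-fold higher, Map2 35.2-fold and Stmn2 at least 8.35-fold lower, Flt1 33.5-fold lower, Itga8 16.6-fold, Nox4 9.96-fold, Actg2 6.88-fold and Atf3 6.18-fold lower. Col2a1 was at least 94.8-fold lower, Cldn4 at least 48.5-fold, Cidea at least 35.8-fold and Epcam at least 16.4-fold higher, Vgf 18.1-fold and Ddit4 5.28-fold higher, and Cox6c and Ndufa1 1.90-fold and 1.57-fold higher. Robo4 had 2 and 1 reads in MEF against 154 and 177 in LC, a ratio of 123 with a counting interval from 41.9 to 601. In these lists without a call, median and mean had opposite signs for smooth muscle (0.193 and -0.448), germ cell (0.068 and -0.939), unfolded protein (0.011 and -0.055) and epithelial genes (-1.106 and 0.107), and camera's direction for chondrocyte genes was up against a median of -0.403. Gata1, which is on both the erythroid and the Sertoli cell list, was at least 37.3-fold higher. Of the skeletal muscle list, Tnnt3 was 4.56-fold lower and Mylpf 3.02-fold higher. The Mylpf call was lost with DESeq2 (adjusted p = 0.0541), without MEF replicate 2 (0.0805) and without LC replicate 2 (0.0583). With single libraries left out, the log2 fold change ran from -10.49 to -7.28 for Gfra1, 7.89 to 9.36 for Acan, 7.98 to 9.37 for Gsta3, 7.40 to 8.87 for Hsd11b1, 7.76 to 10.20 for Tcf21, 1.05 to 2.48 for Mylpf and 1.75 to 9.92 for Insl3.

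In all, 5203 genes were higher and 5108 lower in LC than in MEF, of which 2091 and 1875 changed at least 2-fold. With an assumed coefficient of variation of 0.4 the counts were 1450 and 1058, and the calls of Cox6c (adjusted p = 0.397), Mylpf (0.122) and Ndufa1 (0.702) were lost. No list was called with the block and an estimated correlation together (adjusted p from 0.123). Beyond the lists, the largest rises were those of Serpinb2, at 471 ± 10.9 CPM and 2 reads in MEF (a ratio of 9010 with a counting interval from 2490 to 74400), Slc30a2, a zinc transporter, at least 472-fold higher, Nxf3, at least 431-fold higher, Marco, with 1 and 0 reads in MEF (a ratio of 4890 with a counting interval from 878 to 193000), and the water channel Aqp2, at least 252-fold higher. The choline transporter Slc5a7 was at least 695-fold lower, Chodl at least 549-fold, Cdh8 at least 243-fold, the bone morphogenetic protein antagonist Grem1 at least 197-fold and Reg1 at least 171-fold lower. Estimated reads of Gsta3, Gstm1, Igf2, Lgr5, Dkk2, Ifi44, Pmaip1, Kif20a, Map2, Zbtb16, Actg2, Idi1 and Adm were not whole in at least 1 library and are less certain.

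**Figure D2:**
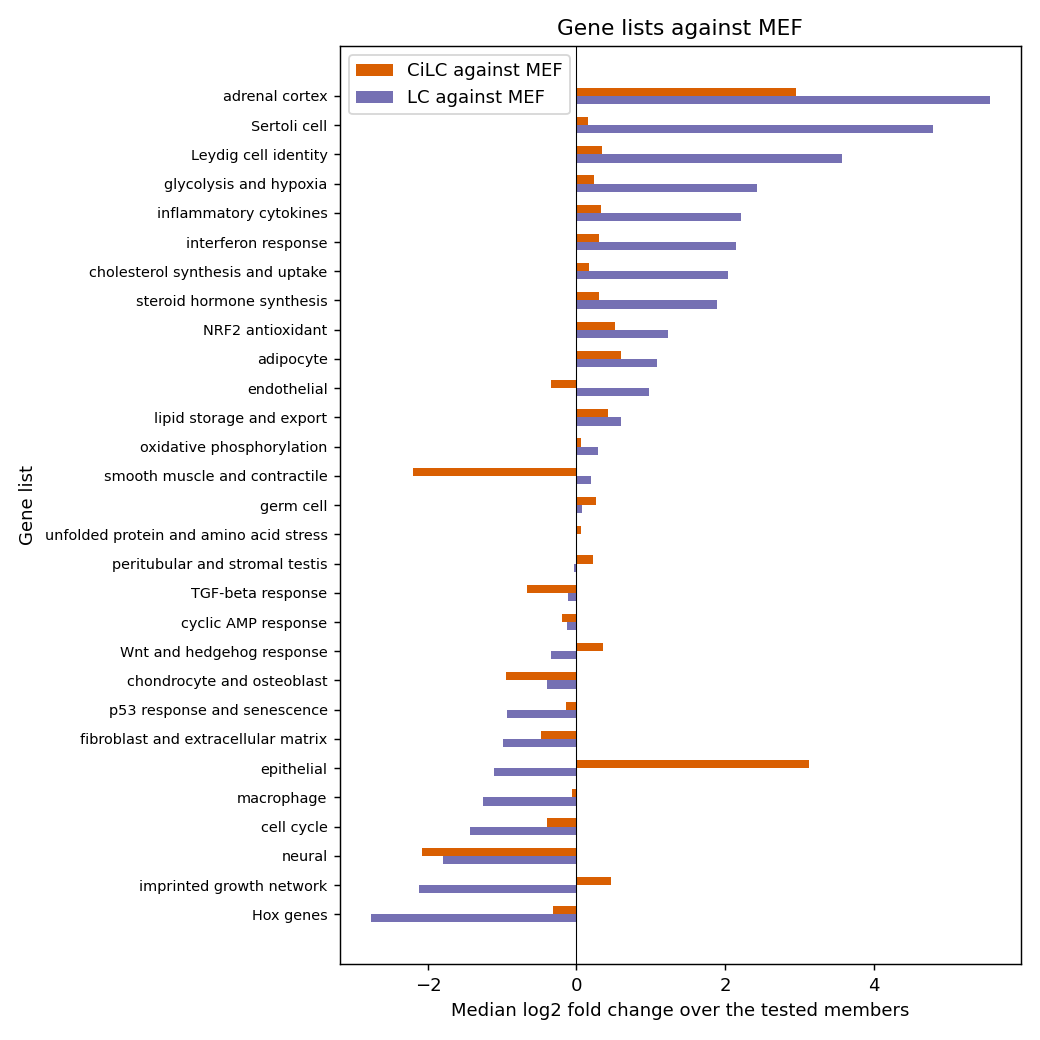
Median log2 fold change over the tested members of each gene list, for CiLC against MEF and for LC against MEF (bars from 0). The smooth muscle and contractile list stood at -2.20 in CiLC and 0.19 in LC, and the cholesterol list at 0.16 and 2.04.

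The comparison of CiLC with LC sets induced beside testis-derived cells. Nr5a1, Star, Hsd3b1 and Cyp11a1, raised in CiLC, stayed below their LC levels. Nr5a1 was 2.40-fold lower in CiLC than in LC (log2 fold change -1.26 ± 0.054 SE, edgeR adjusted p = 1.04e-16) and Star 3.14-fold lower (-1.65 ± 0.055 SE, edgeR adjusted p = 1.02e-18). Hsd3b1 was 5.76-fold lower and Cyp11a1 57.3-fold lower (log2 fold change -5.84 ± 0.08 SE, edgeR adjusted p = 1.71e-26). Insl3 was at 0.558 ± 0.543 CPM in CiLC and 6.55 ± 0.726 in LC (edgeR adjusted p = 2.89e-06; DESeq2 adjusted p = 0.15). Cyp17a1 was at the floor in both groups, and Lhcgr had 0 reads in CiLC against 3 and 2 in LC, at least 1.92-fold lower against the floor. Lhcgr was not tested, and this bound leaves out the counting error of the few LC reads. With an assumed coefficient of variation of 0.4 the Nr5a1 call was lost (adjusted p = 0.158).

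Of 16 steroid hormone synthesis members, 13 were lower and 3 higher in CiLC than in LC (camera adjusted p = 1.27e-07; adjusted p = 0.0981 with an estimated correlation). Ferredoxin (Fdx1) and its reductase (Fdxr), which feed electrons to Cyp11a1, were 11.3-fold and 10.7-fold lower, and Hsd11b1 6.72-fold lower. Akr1c14 was higher in CiLC, at 35.4 ± 1.6 CPM against 9.93 ± 0.885 in LC. Of 23 Leydig cell identity members, 17 were lower, or 18 when adjusted over the list alone, and 5 higher (camera adjusted p = 6.52e-06; adjusted p = 0.0507 with an estimated correlation). Amhr2 was at 0.178 ± 0.0355 CPM in CiLC and 21.1 ± 0.848 in LC, 115-fold lower, Defb36 at least 88.2-fold and Hao2 at least 17.6-fold lower. The cholesterol list was lower in 24 of 24 members (camera adjusted p = 1.19e-15; adjusted p = 0.029 with an estimated correlation), with Fdps 8.02-fold and Msmo1 5.76-fold lower. The adrenal cortex list had 7 of 8 members lower and 1 higher (camera adjusted p = 1.75e-09; adjusted p = 0.0507 with an estimated correlation). Mrap had 1 read in CiLC, a ratio of 4940 with a counting interval from 887 to 195000. Sertoli cell genes were lower in 13 of 14 cases and higher in 1 (camera adjusted p = 4.15e-10; adjusted p = 0.0305 with an estimated correlation), with Defb19 at least 54.1-fold and Cst12 at least 52.5-fold lower.

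Fibroblast, imprinted and Hox genes were among those higher in CiLC than in LC. Of 35 fibroblast and extracellular matrix members, 24 were higher and 9 lower (camera adjusted p = 1.14e-09; adjusted p = 0.0765 with an estimated correlation). Fbn2 was at 561 ± 23 CPM in CiLC, 188-fold above LC, Thy1 at 817 ± 30.3 CPM, 142.5-fold above, Lum 64.8-fold and Postn 54.1-fold above. The imprinted growth network was higher in 14 of 16 members and lower in 2 (camera adjusted p = 6.81e-18; adjusted p = 0.029 with an estimated correlation), with Dlk1 288-fold and Mest 110.4-fold above LC. Hox genes were higher in 24 of 31 cases and lower in 6 (camera adjusted p = 0.000797; adjusted p = 0.0672 with an estimated correlation), with Hoxa11 at least 56.2-fold and Hoxa10 63.2-fold higher. Cell cycle genes were higher in 29 of 30 cases (camera adjusted p = 6.22e-05; adjusted p = 0.0539 with an estimated correlation), with Ccnb2 3.64-fold and Cenpf 3.23-fold higher. Macrophage genes were higher in 17 of 20 and lower in 3 (camera adjusted p = 1.74e-09; adjusted p = 0.0586 with an estimated correlation), with Mrc1 13.3-fold higher and Cd163 3.39-fold lower. In the p53 and senescence list 13 of 18 were higher and 3 lower (camera adjusted p = 0.0016; adjusted p = 0.149 with an estimated correlation), with Cdkn2a 23.4-fold and Pmaip1 6.84-fold higher. In the Wnt and hedgehog list 11 of 17 were higher and 5 lower (camera adjusted p = 0.000189; adjusted p = 0.0638 with an estimated correlation), with Hhip 590.5-fold and Notum at least 46.4-fold higher and Ptch1 lower (log2 fold change -0.85), a list call lost with quantile normalization (adjusted p = 0.0648). In the epithelial list 6 of 9 were higher and 3 lower (camera adjusted p = 0.004; adjusted p = 0.122 with an estimated correlation), a call also lost without LC replicate 1 (adjusted p = 0.053), without a filter (0.171), with quantile normalization (0.0954) and with DESeq2 (0.0642). Krt7 had 1 and 0 reads in LC against 17.9 ± 1.62 CPM in CiLC, a ratio of 614 with a counting interval from 110 to 24300, and Cldn4 was at least 49.8-fold lower.

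Glycolysis, interferon, cytokine, NRF2 and smooth muscle genes were lower in CiLC than in LC. All 22 glycolysis and hypoxia members were lower in CiLC (camera adjusted p = 2.78e-38), with Egln3 13.2-fold and Bnip3 11.4-fold lower. All 18 interferon members were lower (camera adjusted p = 1.21e-12), with Irf7 22.3-fold and Ifi44 14.6-fold lower. Inflammatory cytokines were lower in 17 of 21 and higher in 3 (camera adjusted p = 4.89e-15), with Ccl5 382-fold and Csf3 164.5-fold lower. NRF2 genes were lower in 15 of 18 and higher in 1 (camera adjusted p = 1.2e-11), with Gsta3 81.2-fold and Me1 16.5-fold lower. Smooth muscle genes were lower in 13 of 15 and higher in 2 (camera adjusted p = 1.47e-14), with Mylk, the myosin light chain kinase, at 43.1 ± 0.142 against 734.5 ± 9.7 CPM, and Myh11 15.8-fold lower. These 5 calls held with an estimated correlation (adjusted p from 0.029 to 0.0326) but not with the block and an estimated correlation together (each adjusted p = 0.123), where no list was called. Lower lists whose call did not hold were TGF-beta response (13 lower and 6 higher of 20; camera adjusted p = 0.00163; adjusted p = 0.0981 with an estimated correlation), with Ankrd1 14.3-fold lower and the call lost with quantile normalization (0.0566), and peritubular and stromal genes (11 lower and 4 higher of 15; camera adjusted p = 9.39e-07; adjusted p = 0.122 with an estimated correlation), with Tcf21 38.9-fold lower. Chondrocyte and osteoblast genes were also called as lower (4 lower and 3 higher of 9; camera adjusted p = 0.00792; adjusted p = 0.155 with an estimated correlation). Their median log2 fold change was 0.17, or -0.20 with genes at the floor set to their bound, the mean was -1.17, and the call was lost without LC replicate 1 (adjusted p = 0.197) or LC replicate 2 (adjusted p = 0.309), without a filter (0.677), with quantile normalization (0.236) and with DESeq2 (0.174). Alpl, the phosphatase of mineralizing cells, was 46.3-fold lower, and Acan had 1 read in each CiLC library against 666 and 665 in LC, a ratio of 765 with a counting interval from 211 to 6330.

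The remaining lists were not called between CiLC and LC, with camera adjusted p from 0.071 for lipid storage to 0.911 for cyclic AMP. Higher and lower members were 3 and 8 of 12 for endothelial, 2 and 1 of 6 for germ cell, 3 and 3 of 10 for neural, 3 and 4 of 8 for adipocyte, 6 and 10 of 21 for cyclic AMP, 9 and 7 of 21 for unfolded protein stress, 6 and 12 of 23 for lipid storage and 4 and 15 of 28 for oxidative phosphorylation. The last was called as lower without a filter (adjusted p = 0.0184) and without LC replicate 2 (0.016), the neural list over genes of at least 5 CPM (0.0243) and the endothelial list at an assumed coefficient of variation of 0.4 (0.028). The endothelial cadherin Cdh5 was 12.5-fold lower in CiLC, and Gfra1, a receptor subunit for glial growth factors, was at 74.5 ± 4.96 CPM in CiLC against 1 and 10 reads in LC. Ddx4 was 11.9-fold higher, Ppargc1a 5.96-fold, Trib3 2.06-fold and Stmn2 at least 4.93-fold higher. Tubb3 was 59.9-fold lower, Angptl4 7.23-fold, Ddit4 4.10-fold, Nr4a3 3.75-fold, Ndufa1 1.52-fold and Cidea at least 36.8-fold lower, Plin1 had a log2 fold change of -3.59, and Robo4 had 1 and 0 reads in CiLC, a ratio of 381 with a counting interval from 67.9 to 15100. Camera's direction differed from the sign of the median for neural (down, median 1.061) and adipocyte genes (up, median -0.329). Gata1, of the erythroid and the Sertoli cell list, was at least 38.3-fold lower, and Mylpf of the skeletal muscle list was 3.87-fold lower. Epor of the erythroid list was 2.45-fold lower, a call lost with DESeq2 (adjusted p = 0.079), without CiLC replicate 2 (0.182) and without LC replicate 1 (0.0992). With single libraries left out, the log2 fold change ran from 6.97 to 10.17 for Gfra1, 8.72 to 9.97 for Hhip, 13.09 to 14.59 for Agtr2, -2.28 to -0.71 for Epor and -5.36 to -2.74 for Insl3.

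In all, 5108 genes were higher and 5187 lower in CiLC than in LC, of which 1666 and 2043 differed at least 2-fold. With an assumed coefficient of variation of 0.4 the counts were 937 and 1314, and the calls of Cd163 (adjusted p = 0.0511), Epor (0.271), Ndufa1 (0.776), Ptch1 (0.492) and Trib3 (0.318) were lost. The genes furthest above LC were Reg1, at least 1650-fold higher, Reg3g, at least 1080-fold, Agtr2, an angiotensin receptor at 1592 ± 54 CPM in CiLC with 1 and 3 reads in LC, Edil3, at least 519-fold, Grem1, at least 257-fold, and Gdf10 with 0 and 1 reads in LC, a ratio of 4120 with a counting interval from 740 to 163000. Those furthest below were Hdc, the histamine-forming decarboxylase at 90.6 ± 1.05 CPM in LC and at least 1190-fold lower, Mrap, Aqp2, at least 260-fold lower, Tex19.2, at least 190-fold, Mmd2, at least 160-fold, and Bpifa2, at least 130-fold lower. Estimated reads of Fdx1, Tex19.2, Hsd3b1, Mest, Gsta3, Myh11, Cenpf, Cd163, Tubb3, Ppargc1a, Nr4a3, Pmaip1 and Ifi44 were not whole in at least 1 library and are less certain.

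The overlap of both comparisons against MEF shows how far the changes of CiLC ran with those of LC. Of genes called higher, 2029 were higher in both CiLC and LC, against 1358.8 for independent lists, and 2289 were lower in both, against 1303.5. A further 877 genes were higher in CiLC and lower in LC, against 1334 for independent lists, and 807 lower in CiLC and higher in LC, against 1327.8. Among the 2091 genes at least 2-fold higher in LC, 498 (23.8%) were also at least 2-fold higher in CiLC, against 130.2 for independent lists, as were Nr5a1, Star and Cyp11a1, and 113 (5.4%) at least 2-fold lower, against 125. Among the 1875 genes at least 2-fold lower in LC, 469 (25%) were at least 2-fold lower in CiLC, against 112.1 for independent lists, as was Rgs5. A further 153 (8.2%) were at least 2-fold higher, as was Dlk1, a number also above the 116.8 for independent lists. Both comparisons use the same MEF libraries. In 20 simulations of unchanged groups, at the spread fitted to these libraries, no gene was called in both. With no gene changed hardly any gene can be called, so that result gives no reference for the overlap. Across 13737 genes, which are not independent replicates, the fold changes correlated at 0.382 and their covariance was 0.467. The simulations gave a mean correlation of 0.49 and a mean covariance of 0.0125. With no gene changed, noise in the shared MEF libraries alone sets that correlation, so it gives no reference for the observed correlation. The simulated covariance was at most 0.0137, which argues against the spread between the MEF libraries as the main source of the observed covariance. Traits common to both MEF libraries are not covered by that spread. A split of the 2 MEF libraries would leave a single library on each side and was not made, so part of the excess may still come from sharing them.

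**Figure D3:**
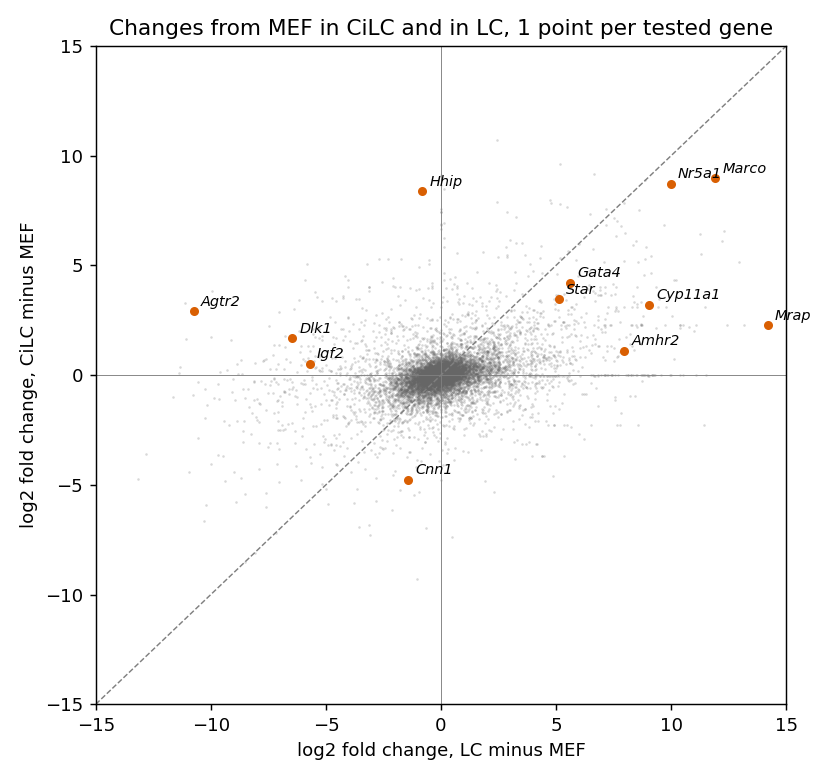
Log2 fold change of each tested gene in LC minus MEF (horizontal axis) and CiLC minus MEF (vertical axis), with 12 genes labelled in orange and the line of equal change dashed. Nr5a1, Gata4 and Star lay below the line, short of the change in LC, but closer to it than Cyp11a1, Amhr2 and Mrap. Those lay far to the right of the line, and Hhip lay far above it. Values of genes with few reads in a group, Mrap and Amhr2 among them, depend on the prior count.

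Across all tested genes, CiLC libraries lay closer to MEF than to LC. The mean Pearson correlation of log2(CPM + 1) was 0.957 between CiLC and MEF (4 pairs, 0.957 to 0.958), 0.880 between CiLC and LC (0.879 to 0.881) and 0.861 between LC and MEF (0.860 to 0.862). Libraries of the same group correlated at 0.997. The first principal component, with 78.6% of the variance, set LC apart from the other groups, and the next, with 19.4%, parted CiLC from MEF. As a check of the labels, Y-linked genes were read in every library. Ddx3y stood at 13.4 ± 2.37 CPM in MEF, 22.9 ± 2.2 in CiLC and 52.6 ± 4.06 in LC, Uty at 6 ± 0.456, 9.13 ± 0.0979 and 18.1 ± 0.117, Kdm5d at 7.36 ± 0.469, 9.28 ± 0.0275 and 24.9 ± 0.446, and Eif2s3y at 12.2 ± 0.528, 15.2 ± 1.52 and 42.0 ± 2.51 CPM. Their estimated reads were not whole in any library. All 4 genes were detected in every library, and the cause of their differences between groups was not tested. Ddx3y was 1.71-fold (edgeR adjusted p = 1.41e-06) and Uty 1.52-fold (edgeR adjusted p = 0.000227) higher in CiLC than in MEF, calls lost only at an assumed coefficient of variation of 0.4. The rises of Kdm5d and Eif2s3y in CiLC over MEF were lost with DESeq2 and without CiLC replicate 2 or MEF replicate 2 (adjusted p from 0.0621 to 0.179), and that of Kdm5d also without CiLC replicate 1 (adjusted p = 0.0684). Both were lost at an assumed coefficient of variation of 0.1 (adjusted p = 0.173 and 0.166), and at 0.4 none of the differences of the 4 genes between CiLC and MEF or LC was called (0.0788 to 1).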

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

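The assumed coefficients of variation were chosen after seeing the data, and the other settings were fixed before. A pseudocount for the tests was not run, because the values were counts. Requiring a 2-fold change gave 908 higher and 872 lower genes for CiLC against MEF, 2091 and 1875 for LC against MEF, and 1666 and 2043 for CiLC against LC, fewer by construction. It left 498 genes higher and 469 lower in both CiLC and LC, 153 higher in CiLC and lower in LC, and 113 the other way. An assumed coefficient of 0.1 gave 2064 and 2141 genes for CiLC against MEF, 1087 and 1337 in both and 395 and 361 in opposite directions. At 0.4 the counts were 407 and 268 for CiLC against MEF, 1450 and 1058 for LC against MEF, 937 and 1314 for CiLC against LC, 205 and 165 in both and 51 and 15 in opposite directions. Both assumed values came with a likelihood ratio test in place of the quasi-likelihood test, so spread and test changed together, and the cause was not tested. DESeq2 found 576 genes higher in CiLC and lower in LC, against 877, and the cause was not tested. All other counts of genes stayed within 1.5 times. Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 3021 to 3718 higher and 3090 to 3668 lower genes for CiLC against MEF. Estimated correlations left 4, 10 and 8 lists called for CiLC against MEF, LC against MEF and CiLC against LC, in place of 22, 17 and 21. With the replicate number as a block the counts were 3791 and 3714 genes for CiLC against MEF and 19, 17 and 21 lists. Block and estimated correlation together called 0, 0 and 0 lists, with many lists tied at a camera adjusted p of 0.123. With an estimated correlation camera has only the few residual degrees of freedom of the fit, and the block leaves fewer still. Smooth muscle genes in CiLC against MEF went from a camera adjusted p of 4.2e-45 to 0.029 at an estimated correlation of -0.0619. Whether the degrees of freedom alone ended the calls was not tested. Some lists lost their call in CiLC against MEF with an estimated correlation alone, although that correlation was negative. These included the imprinted growth network (-0.0632), Wnt and hedgehog (-0.0591) and cell cycle lists (-0.0168). Such values argue against correlated members as the cause for these lists. Other lists that lost their call, such as steroid hormone synthesis (0.1359), had a positive correlation. Libraries of the same number did not deviate together (correlations across genes of 0.089 for CiLC and MEF, 0.025 for LC and MEF and -0.077 for CiLC and LC), so the number is not taken as pairing. Mean correlations between CiLC and MEF, CiLC and LC, and LC and MEF were 0.946, 0.845 and 0.826 with a log offset of 0.1, 0.961, 0.891 and 0.871 with an offset of 5, 0.975, 0.929 and 0.918 without a filter, 0.926, 0.79 and 0.754 for genes of at least 5 CPM, and 0.959, 0.891 and 0.873 by Spearman, in the same order each time. Some directions turned, and the cause was not tested. Without single libraries the log2 fold change ranged from -2.617 to 6.39 for Insl3 and from -0.064 to 0.23 for Fdx1 in CiLC against MEF, and in LC against MEF from -0.107 to 0.033 for Notch3, from -0.148 to 0.026 for Lyz2 and from -0.772 to 3.273 for Wif1. It was 0 for Insl3 without CiLC replicate 2. Adgre1 in LC against MEF turned to -0.057 with quantile normalization. Lists turned only where camera called them in neither setting, at the adjusted p given here. Without a filter these were smooth muscle (0.928), germ cell (0.549) and chondrocyte genes (0.555) in LC against MEF, and germ cell (0.847) and neural genes (0.928) in CiLC against LC. With quantile normalization they were chondrocyte genes in LC against MEF (0.921) and adipocyte genes in CiLC against LC (0.722). Chondrocyte genes in LC against MEF also turned with DESeq2 (0.646), with only the 4 libraries compared (0.811), with the block (0.962), with block and estimated correlation (0.965), at a coefficient of 0.4 (0.769) and without either CiLC (0.825 and 0.823) or LC library (0.773 and 0.836; 0.684 to 0.836 over all libraries). Smooth muscle genes turned without either LC library (0.99 and 0.92; 0.479 to 0.99 over all), as did adipocyte genes in CiLC against LC (0.941 and 0.897; 0.405 to 0.941 over all), and unfolded protein genes in CiLC against MEF turned without MEF replicate 2 (0.881; 0.286 to 0.881 over all). At coefficients of 0.1 and 0.4 unfolded protein genes (0.966 and 0.931), adipocyte genes (0.778 and 0.329) and cyclic AMP genes in CiLC against LC (0.966 and 0.925) turned. Cyp17a1 and Lhcgr were near absent in all groups, with at most 3 reads in any library, so any difference between groups rests on a few reads.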

Other observations

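All tests in this part were chosen after the results were seen, as were the genes named here outside the fixed rule. At least 2-fold beyond both other groups stood 396 genes higher and 326 lower in CiLC. Among those higher, Cyp2f2, a cytochrome P450 of airway cells, was at 569 ± 14.1 CPM (SD, n = 2) in CiLC, 16.9 ± 0.765 in MEF and 0.293 ± 0.251 in LC. The lipocalin Apod was at 532 ± 5.47, 23.2 ± 0.097 and 1.28 ± 0.035 CPM, and the prostaglandin receptor Ptgfr at 80.8 ± 1.81, 4.96 ± 0.432 and 1.43 ± 0.019 CPM. The proteases Mmp9 and Mmp13 were picked from these genes, with Mmp9 at 373 ± 12.1 CPM against 1.46 ± 0.66 in MEF and 39.3 ± 1.45 in LC, and Mmp13 at 115 ± 2.37 against 10.6 ± 0.24 and 7.3 ± 0.91 CPM. The mesothelial genes Msln and Upk3b were at 37.4 ± 0.31 and 34.4 ± 3.14 CPM in CiLC, against 4.28 ± 0.72 and 3.05 ± 0.69 in MEF. Among those lower, Prss35 was at 8.24 ± 0.18 CPM in CiLC, 68.9 ± 1.09 in MEF and 963 ± 3.61 in LC. The hypoxia-inducible factor Epas1 was at 16.9 ± 0.4, 76.8 ± 1.59 and 187 ± 0.49 CPM, and Notch3, a receptor of mural cells, at 26.7 ± 0.32, 116 ± 7.54 and 113 ± 2.53 CPM. Estimated reads of Apod, Ptgfr, Prss35 and Epas1 were not whole in most libraries and are less certain.

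The first pattern weighed is the rise of Nr5a1, Gata4, Star, Cyp11a1 and Hsd3b1 in CiLC, which reached 41.6%, 36.6%, 29.8%, 1.56% and 15.7% of the difference between LC and MEF. RNA or cells from the LC cultures would bring their other abundant transcripts in the same share. The 33 other genes at 50 CPM or more in LC and at most 1 CPM in MEF reached a median of 0.91% (quartiles 0.16% and 2.3%). That argues against such a source for Nr5a1, Gata4, Star and Hsd3b1, although Acod1 reached Nr5a1's share and Apln, at 34.5%, that of Star. For Cyp11a1 it is argued against as well, since 21 of the 33 lay below the share that Cyp11a1 alone would need. Among these were Akr1cl (-0.037%), Hdc (-0.029%) and Mrap (0.02%). Reads shared between related genes are also argued against for Nr5a1, Gata4, Star and Cyp11a1, where 0 values in the 6 libraries were not whole, but not for Hsd3b1. Induction in fibroblasts and growth of a few such cells present in the MEF cultures were not tested apart, and both stay open.

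The next pattern is the high level of Sertoli cell genes in LC, beside near absent Lhcgr and Cyp17a1. Clu was at 1942 ± 3.8 CPM in LC, Wt1 at 123 ± 1.15, Cldn11 at 118 ± 2.46, Sox9, with values that were not whole, at 46.3 ± 1.69 and Dhh at 13.1 ± 1.6 CPM. Reads shared between related genes are argued against, since 3 of the 14 members that rose had values that were not whole in LC. Sertoli cells within the cultures may contribute, since 14 of 19 members were above 1 CPM in both LC libraries, but Rhox5, Cst9 and Tsx had 2 reads each, Nr0b1 3 and Fshr 12. That cannot be told apart from gene loss or gain in cultured Leydig cells, because culture and group coincide, and Wt1 is also on the peritubular list.

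The last pattern is that macrophage genes moved apart between MEF and CiLC. Lyz2 rose from 2660 ± 39.3 to 7571 ± 122 CPM and Adgre1 from 166.5 ± 8.78 to 367 ± 10.7 CPM, while C1qa fell from 738 ± 2.45 to 351 ± 18.8 and C1qc from 537 ± 1.59 to 210 ± 10.8 CPM, changes not called at an assumed coefficient of variation of 0.4 (adjusted p from 0.158 to 0.607). A change in the share of macrophages alone would move them one way, and 5 members rose while 9 fell. Reads shared between related genes are argued against as the whole cause, since 4 of the 14 called members had values that were not whole in CiLC or MEF, Lyz2 and Cx3cr1 among them. A change of macrophage state, and a change in share on top of it, were not tested and stay open.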
